A study of Homo sapiens with 12 samples.

How the data were processed

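The series holds RNA-seq of innate lymphoid cells (ILCs) sorted from human tonsil, with 12 libraries from 4 sorted populations and 3 batches. Per the labels' protocols, tonsils were broken up mechanically, CD56-positive cells were enriched on beads and sorted, RNA was isolated with a micro-scale column kit, and cDNA was made with a SMARTer low-input kit before Illumina sequencing. All 4 populations were sorted as CD56 and NKp44 positive. ILC3a were CD196 and CD300LF positive and CD103 negative. ILC3b were positive for CD196, CD300LF and CD103. ILC1b were CD196 and CD103 positive and CD300LF negative. ILC1a were CD103 positive and negative for CD196 and CD300LF.

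The deposited values are raw read counts per Ensembl gene, whole numbers in 1 column per library. Reads were aligned with STAR to hg19, per the submitters' processing notes; the STAR version, the counting tool, its strand setting and the annotation release are not given in the sources used here. The deposited table has 54087 lines for 53721 gene IDs. The 332 IDs that stood on more than 1 line had identical counts on each (0 differed) and were counted once. Gene symbols, biotypes and Ensembl IDs were taken from the deposited table. The reference annotation used here, GENCODE 29 on GRCh38, held 51537 of the IDs and is on another genome build, so no coordinates are given. It served only to find genes of the Y chromosome, which were left out of every output together with XIST and TSIX. The 540 symbols with more than 1 ID were kept as separate IDs, the second and later of which held 0.075% of the counts.

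Several abundant genes are listed at 0 in all 12 libraries, among them NCAM1, LTB, TNF, NCR1, NCR3, TPI1, RPL7A, RPS9, RPS18, HLA-DPA1 and TRBC1. Ribosomal protein and glycolysis genes in that set are used by every cell, so a 0 of this kind is not read as absence. CCL3, CCL4 and TRAC were not analysed here. Reads of near-identical copies can be split or dropped in counting, so values for FCGR3A (near copy FCGR3B), KLRC2 and KLRC3, GZMB and GZMH, and the haemoglobin genes carry that uncertainty. Without a stated strand setting, reads of overlapping and antisense genes cannot be told apart.

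Totals ran from 8328763 to 24492405 counts. Intervals (95%) and floors (3 counts over the 3 libraries of a group) cover counting error only, since PCR copies are not independent molecules. A gene at 0 counts in a group is given as a lower bound of its fold against that floor, and a gene at 1 to 3 counts as a ratio with its counting interval. Genes detected were also counted after thinning every library at random to 8328763 counts. Replicate libraries of a group differed by 40.7 to 273.1 in chi-square per gene, far beyond sampling noise, and all 12 were kept as separate samples. Nothing in the labels says how the batches relate to donors beyond calling the samples biological replicates.

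The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16 in R 4.3.3, glmQLFit with robust estimation and glmQLFTest) with TMM scaling and filterByExpr by group, which kept 16527 genes. All 12 libraries entered 1 fit with group as the only term. Genes were called at a Benjamini-Hochberg adjusted p of 0.05, and every adjusted p of a gene given below comes from this test unless another is named. Fold changes are log2 values with their standard errors, and levels are CPM (edgeR's cpm function on TMM-scaled totals), mean ± SD over 3 libraries. The limits for missing genes, the floors and the ratios at 1 to 3 counts use totals without TMM scaling. Log2 CPM used a prior count of 2. The comparisons are the 4 main ones, ILC1a against ILC3a and the 3 steps between neighbours in the marker series, then the other 2 pairs and a joint test of the 4 populations. There were 30 gene lists. Those of lineage and function were ILC3 program, effector and cytotoxic genes, NK receptors, tissue residency, tissue egress, lymphocyte transcription factors, cytokine receptors, chemokine receptors, TGF-beta response, Notch, checkpoint and costimulatory receptors, MHC class II and interferon response. Those of cell state and RNA quality were proliferation, glycolysis, oxidative phosphorylation, ribosomal proteins, immediate early genes and mitochondrially encoded genes. Those of other cells and checks were T cells, gamma-delta T-cell receptor, circulating NK cells, ILC2, B cells, plasma cells, myeloid cells, mast cells and granulocytes, epithelial and stromal cells, erythroid cells and platelets, and the sort markers. Of these, 28 were tested with limma's camera (limma 3.58.1, voom values) at a preset correlation of 0.01, and again with an estimated correlation, adjusted over lists within a comparison. Camera sets a list against all other genes, so its direction (up or down, higher or lower by camera) is relative to them. The mast cell and granulocyte list was not tested, as 1 of its 9 genes was measured, and the sort markers served as a check of the labels.

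Gene lists, comparisons, thresholds and the rule for named genes were fixed before the data were examined. The rule took, per main comparison, the 12 highest and 12 lowest log2 fold changes among called genes that moved the same way in all 3 batches, had a mean of at least 10 CPM in the higher group and a proper gene symbol. It added up to 4 called members per direction of each list described, and 7 transcription factors and 4 effector genes that are always given. Some of the genes this rule names are not reported here. The position of a middle population was measured on genes called between ILC3a and ILC1a in the other 2 batches, as the mean signed log2 CPM scaled to 0 at ILC3a and 1 at ILC1a of the batch scored.

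The labels mark the replicate number as a batch, so same-numbered libraries were taken as paired. Their deviations from the group means had a median correlation across genes of 0.127 (0.06 to 0.258, 18 pairs, of which 11 were above 0.1), against -0.065 for 36 pairs with different numbers. Deviations from a group mean cancel over its libraries, so the value for different numbers largely follows from the other and is no separate baseline. A fit with the batch as a block was run as an alternative, and its value stands beside a result where it changes the call. Other alternatives were DESeq2 1.42.0, limma voom, DESeq2's size factors, no filter, a filter of 50 counts in 3 libraries, a fit of the compared groups alone, other gene set tests, other choices of position genes, and leaving out each library or batch in turn. Sample quality weights, the pairwise fit with a block, the omission of libraries outside the compared pair, and position genes from the end populations alone were added after the data were seen. Tables were handled with Python 3.11.15 and pandas 2.3.3, and plots drawn with matplotlib 3.10.9.

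The procedure was tested on simulated counts for ILC1a against ILC3a, with 100 genes changed 4-fold and 100 changed 16-fold. With the spread of all 12 libraries and 15826 genes, 18% of the 4-fold and 60% of the 16-fold changes were recovered, with 1 false call among 79. With the spread of the 6 ILC3a and ILC1a libraries and 15924 genes, 86% and 98% were recovered, with 7 false calls among 191. With the spread of those 6 end libraries, simulated positions of 0.2 and 0.7 were recovered as 0.196 and 0.703. All changed genes of a population shared the same position there. The larger spread and sparser detection of the real ILC3b and ILC1b libraries were not simulated, so the recovery does not cover them.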

Results

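RNA was sequenced from 4 populations of CD56-positive, NKp44-positive innate lymphoid cells of human tonsil, tissue-resident lymphocytes without rearranged antigen receptors. The sort placed them in a series whose neighbours differ in 1 further surface protein. ILC3a and ILC3b differ in CD103 (the integrin chain ITGAE), ILC3b and ILC1b in CD300LF, and ILC1b and ILC1a in CD196 (the chemokine receptor CCR6). Each population had 3 libraries, 1 in each of 3 batches. Total counts in replicates 1 to 3 were 16283580, 14551050 and 24492405 in ILC3a and 8328763, 11971960 and 17483570 in ILC3b. They were 10779670, 12469810 and 12079486 in ILC1b and 17644723, 15917557 and 16919744 in ILC1a. The middle populations had sparser libraries. With every library thinned to 8328763 counts, 22009 ± 351 genes were detected in ILC3a, 15931 ± 1951 in ILC3b, 17357 ± 1262 in ILC1b and 20814 ± 910 in ILC1a (mean ± SD, n = 3). Replicates also differed more in the middle populations, by 92.8 to 273.1 in chi-square per gene, than in ILC3a and ILC1a, where the values were 40.7 to 54.9. The share of counts on mitochondrially encoded genes was 4.32 ± 1.54% in ILC3a, 5.87 ± 0.81% in ILC3b, 4.70 ± 1.12% in ILC1b and 3.67 ± 0.67% in ILC1a.

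**Figure D1:**
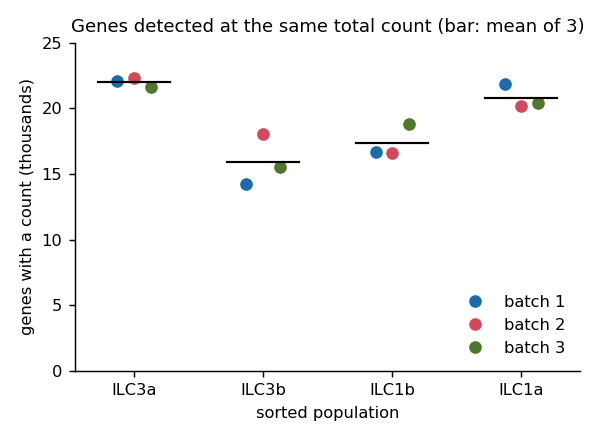
Genes detected per library (axis from 0) with every library thinned to 8328763 counts, as 1 point per library in each of the 4 populations. The 6 libraries of ILC3b and ILC1b lie between 14228 and 18812 genes and the 6 of ILC3a and ILC1a between 20156 and 22335.

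The genes of the sorted surface proteins were examined first, as a check of the labels. ITGAE (ENSG00000083457) stood at 67.5 ± 11.6 CPM in ILC3a, 277 ± 54.4 in ILC3b, 522 ± 49.8 in ILC1b and 742 ± 59.5 in ILC1a (n = 3 each). CD300LF (ENSG00000186074) stood at 820 ± 107 and 593 ± 283 CPM in ILC3a and ILC3b, and at 6.15 ± 9.49 and 0.604 ± 0.418 CPM in ILC1b and ILC1a. CCR6 (ENSG00000112486) had 319 ± 107, 314 ± 140 and 311 ± 159 CPM in ILC3a, ILC3b and ILC1b and 44.6 ± 19.4 CPM in ILC1a. Each step's own marker differed in the direction of the gate. ITGAE rose by 2.04 ± 0.19 log2 units from ILC3a to ILC3b (adjusted p = 0.00771), and CD300LF changed by -6.60 ± 1.24 from ILC3b to ILC1b (adjusted p = 0.0445). The difference in CCR6 from ILC1b to ILC1a (-2.80 ± 0.51) missed the threshold (adjusted p = 0.225) and passed it with the batch as a block (adjusted p = 0.0167). NCR2 (ENSG00000096264), which encodes NKp44, was present in all 4 at 707 ± 175, 1231 ± 242, 648 ± 194 and 305 ± 74.7 CPM. Its difference between ILC1a and ILC3a (-1.21 log2 units) had an adjusted p of 0.0784, or 0.00581 with the block, and its difference between ILC1b and ILC3b (-0.92) had an adjusted p of 0.173, or 0.0469 with the block. NCAM1, which encodes CD56, is listed at 0 in every library and checks nothing.

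**Figure D2:**
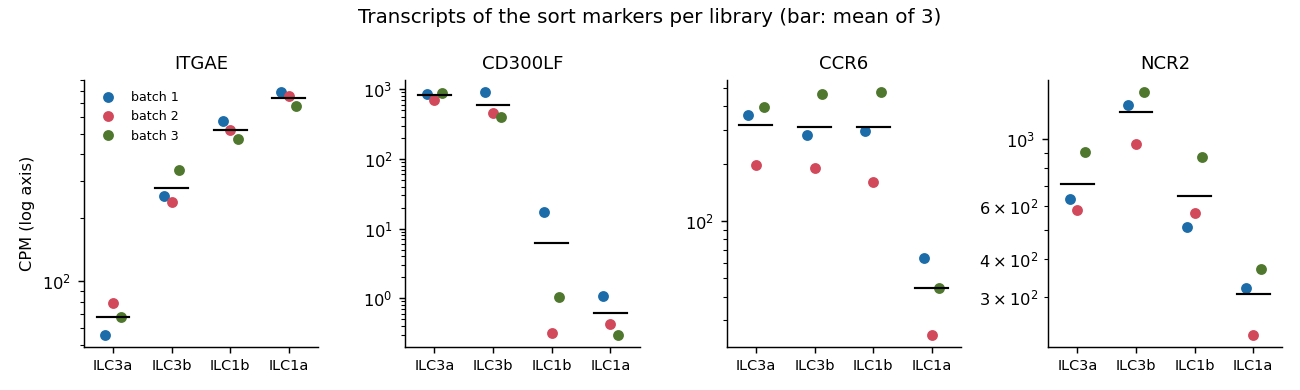
Expression of ITGAE, CD300LF, CCR6 and NCR2 in CPM on a log axis, 1 panel per gene, with 1 point per library and a bar at the mean of 3. Mean ITGAE is 67.5 CPM in ILC3a and 742 CPM in ILC1a, mean CD300LF is 593 CPM in ILC3b and 6.15 CPM in ILC1b, and mean CCR6 is 311 CPM in ILC1b and 44.6 CPM in ILC1a.

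ILC1a against ILC3a compares the ends of the marker series. GZMB (ENSG00000100453), the protease granzyme B, went from 31.9 ± 6.49 to 2050 ± 680 CPM (6.00 ± 0.34 log2 units, adjusted p = 2.94e-05). PRF1 (ENSG00000180644), the pore-forming perforin, went from 11.9 ± 2.99 to 1220 ± 93.8 CPM (6.68 ± 0.82, adjusted p = 0.00242). IFNG (ENSG00000111537), the cytokine interferon gamma, went from 0.895 ± 0.147 to 254 ± 79.2 CPM (8.13 ± 0.64, adjusted p = 0.000247). Of the 4 factors that direct type 1 and cytotoxic lymphocytes, TBX21 (ENSG00000073861) rose by 7.58 ± 0.77 log2 units to 47.3 CPM (adjusted p = 0.000706) and EOMES (ENSG00000163508) by 6.40 ± 0.69 to 154 CPM (adjusted p = 0.00124). IKZF3 (ENSG00000161405), which encodes Aiolos, rose by 7.76 ± 1.24 to 339 CPM (adjusted p = 0.0116) and ZNF683, which encodes Hobit, by 8.01 ± 0.89 to 1331 ± 681 CPM (adjusted p = 0.00132). AHR (ENSG00000106546), a ligand-activated factor of ILC3, fell from 369 ± 51.0 to 54.5 ± 6.04 CPM (adjusted p = 0.000393), and TCF7 (ENSG00000081059), a factor of early and memory lymphocytes, from 1223 ± 55.0 to 317 ± 47.5 CPM (adjusted p = 0.000706). GATA3 (ENSG00000107485) had 67.4 ± 10.1 and 59.9 ± 3.07 CPM, a difference of -0.17 ± 0.33 log2 units. IL22 (ENSG00000127318), the hallmark ILC3 cytokine, averaged 734 ± 1097 CPM in ILC3a, with libraries from 67.1 to 2000 CPM, and 1.24 ± 1.00 in ILC1a. It did not pass in the fit of all libraries (-9.19 ± 2.43, adjusted p = 0.139) and passed in a fit of the compared populations alone (adjusted p = 0.00822).

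**Figure D3:**
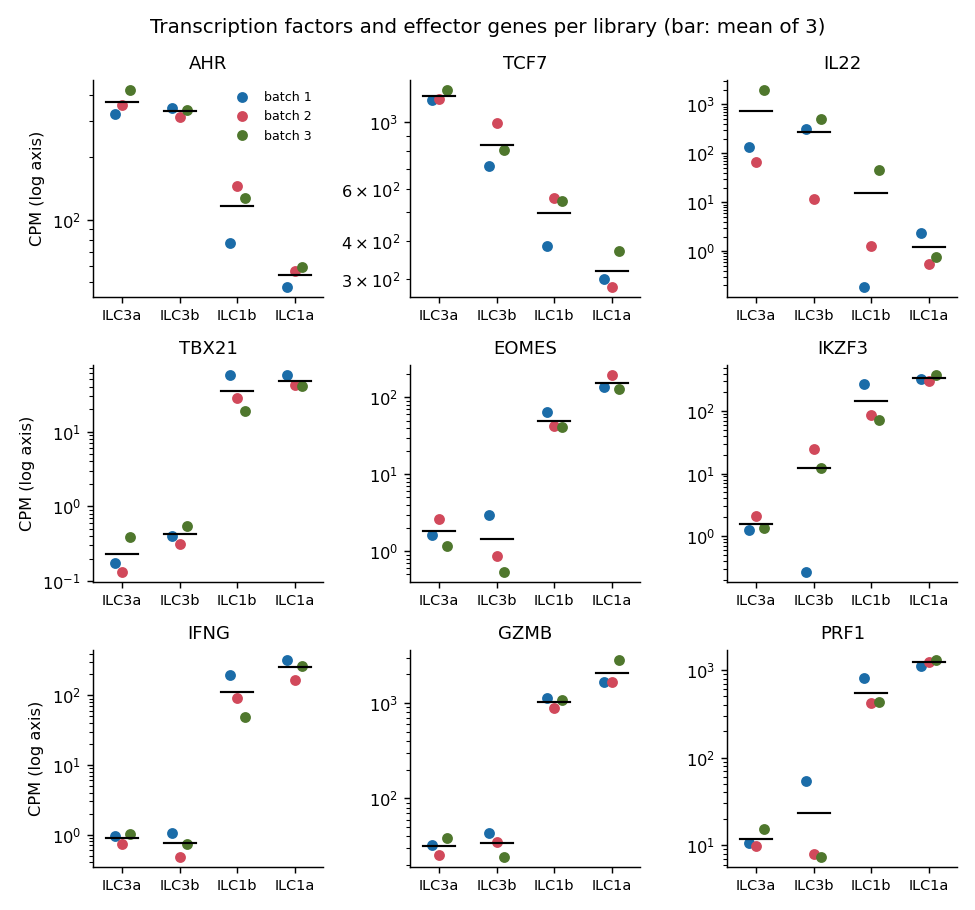
Expression of AHR, TCF7, IL22, TBX21, EOMES, IKZF3, IFNG, GZMB and PRF1 in CPM on a log axis, 1 panel per gene, with 1 point per library, a bar at the mean of 3, and values under 0.05 drawn at 0.05. Mean AHR was 369, 332, 117 and 54.5 CPM from ILC3a to ILC1a, and mean GZMB was 31.9, 34.1, 1023 and 2050 CPM.

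Among the other genes with the highest fold changes in ILC1a were receptors of cytotoxic lymphocytes. FCGR3A, the Fc receptor CD16, went from 0.177 to 171 ± 127 CPM (9.86 ± 1.35 log2 units, adjusted p = 0.00472). FCRL6, an Fc receptor-like protein, went from 0.529 to 270 ± 147 CPM (9.00 ± 1.12), and KLRF1, the activating receptor NKp80, from 3.61 to 809 ± 168 CPM (7.82 ± 1.22). ITGA1, the collagen-binding integrin chain CD49a, reached 312 ± 150 CPM from 1.23 (7.98 ± 1.51). PYHIN1, an interferon-inducible protein, reached 213 ± 28.6 CPM from 0.594, and BCL11B, a factor of T-cell and ILC development, 34.3 ± 9.65 CPM from 0.122. SHISAL1 reached 17.5 ± 9.81 CPM from 0.0702. DRAXIN, a guidance protein, reached 29.4 ± 22.3 CPM from 0.123 (adjusted p = 0.0251, or 0.0530 with the block). CDHR1 and the adrenergic receptor ADRB1 had 2 counts each in ILC3a and 19.4 ± 1.60 and 11.6 ± 3.02 CPM in ILC1a, ratios of 538 (95% counting interval 148 to 4445) and 317 (87.4 to 2626). The genes with the largest falls included the interleukin-23 receptor IL23R (893 ± 130 to 11.7 ± 7.03 CPM, -6.25 ± 0.65), the chemokine CCL20 (130 ± 74.5 to 1.30 ± 0.335 CPM, -6.64 ± 0.79) and NRP1, a semaphorin receptor (283 ± 114 to 2.01 ± 2.17 CPM, -7.14 ± 1.03). The antiprotease SERPINA1 fell from 360 ± 211 to 2.68 ± 0.992 CPM, and the ectonucleotidase NT5E, the sorting receptor SORCS1 and KIAA1217 fell from 24.9, 24.5 and 47.5 CPM to 0.172, 0.141 and 0.116 CPM. AFAP1L1, LDLRAD3 and RNF152 had 3 counts each in ILC1a and 49.7 ± 9.08, 34.0 ± 11.3 and 28.3 ± 9.85 CPM in ILC3a, ratios of 879 (301 to 4266), 570 (195 to 2766) and 516 (176 to 2507). Their adjusted p-values of 0.0423, 0.0330 and 0.0374 became 0.0614, 0.0720 and 0.0637 with the block.

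Of 19 measured effector and cytotoxic genes, 12 rose and 0 fell over all genes tested, and 17 rose and 1 fell (TNFSF10, 388 to 134 CPM, adjusted p = 0.0473 over all genes with the block) adjusted over the list alone (camera adjusted p = 2.75e-31, and 0.000434 with an estimated correlation). They included granzyme H, GZMH (0.469 to 86.1 ± 62.2 CPM, 7.49 ± 0.88), and the chemokine CCL5, with 2 counts in ILC3a and 5.75 ± 0.924 CPM in ILC1a (ratio 158, 43.5 to 1314). Of 20 ILC3 program genes, 0 rose and 10 fell, and 15 fell adjusted over the list alone (camera adjusted p = 4.91e-23, and 0.000407 with an estimated correlation), with NRP1, CCL20 and IL23R among those with the largest fold changes. Of 22 NK receptors, 9 rose and 1 fell, and 13 rose and 2 fell adjusted over the list alone (camera adjusted p = 7.46e-15, and 0.000407 with an estimated correlation). Besides FCGR3A and KLRF1, SLAMF7 rose from 7.20 to 553 ± 132 CPM and KLRC3 from 0.908 to 53.4 ± 11.5 CPM, while KLRF2, which encodes NKp65, fell from 89.9 ± 17.9 to 30.4 ± 9.83 CPM. Of 15 tissue residency genes, 5 rose, and 10 adjusted over the list alone, with 0 falling (camera adjusted p = 4.63e-11, and 0.00066 with an estimated correlation). Besides ZNF683 and ITGA1, the tetraspanin CD9 rose from 5.26 to 180 ± 46.5 CPM and the signalling regulator RGS1 from 1487 ± 399 to 3846 ± 617 CPM. Of 40 lymphocyte transcription factors, 6 rose and 5 fell, and 13 rose and 8 fell adjusted over the list alone, so the list had no common direction (camera adjusted p = 0.597, with a median below 0 and a test direction above 0). The falling ones besides AHR included TOX2 (60.1 ± 2.62 to 2.91 ± 2.47 CPM) and MAF (112 ± 41.5 to 5.51 ± 2.90 CPM). Of 12 egress genes 1 rose and 2 fell, and 2 rose and 3 fell adjusted over the list alone (camera adjusted p = 0.372). LEF1, a factor related to TCF7, rose from 0.840 to 29.4 ± 16.8 CPM (adjusted p = 0.0161, or 0.0506 with the block), and the lymph-node homing receptor CCR7 fell from 545 ± 261 to 66.9 ± 42.3 CPM.

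Of 6 circulating NK cell genes, GZMH and FCGR3A rose over all genes tested and 5 adjusted over the list alone (camera adjusted p = 4.22e-09, and 0.00473 with an estimated correlation). Of 14 T-cell genes, CD3G rose from 7.20 ± 2.75 to 149 ± 51.7 CPM and THEMIS, a T-cell signalling protein, fell from 119 ± 56.5 to 8.14 ± 5.42 CPM, and 5 rose and 2 fell adjusted over the list alone. The camera call for that list (up, adjusted p = 0.0352) was lost with an estimated correlation (adjusted p = 0.358 with an estimated correlation). Of 8 B-cell genes 0 passed over all genes tested and 1 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.541), with MS4A1 at 4.27 and 155 CPM and CD79A at 37.9 and 4.35 CPM in ILC3a and ILC1a. The myeloid list (8 genes) and the epithelial and stromal list (6 genes) were lower in ILC1a by camera (both adjusted p = 0.0114), with adjusted p = 0.155 and adjusted p = 0.0816 with an estimated correlation. In the latter PECAM1, an adhesion protein of endothelium and leukocytes, fell from 500 ± 28.0 to 215 ± 43.5 CPM. The erythroid and platelet list (3 genes) was higher by camera (adjusted p = 0.00521, and adjusted p = 0.155 with an estimated correlation), with HBA2 at 0.0130 and 0.557 CPM. The gamma-delta T-cell receptor, ILC2 and plasma cell lists had camera adjusted p-values of 0.941, 0.564 and 0.541.

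In edgeR's quasi-likelihood test, 198 of 16527 genes differed between ILC1a and ILC3a, 112 higher and 86 lower in ILC1a. The number depends on which libraries enter the fit: a fit of the 6 compared libraries alone called 1998 genes, which included all 198. EdgeR's count over all libraries became 98, 99 and 93 without ILC3a replicate 1, 2 or 3, 97, 110 and 98 without ILC1a replicate 1, 2 or 3, and 363 without ILC3b replicate 1. It was 93, 23 and 15 without the whole of batch 1, 2 or 3. The balance of higher and lower genes also depended on the setting. DESeq2 called 325 higher and 359 lower, the fit of the 6 libraries alone 950 and 1048, and edgeR without ILC3a replicate 1, 2 or 3 called 46 and 52, 44 and 55, and 44 and 49.

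ILC3b against ILC3a compares cells sorted as CD103 positive and CD103 negative within the CD300LF-positive gate. Apart from ITGAE itself, 3 genes passed. NELL2, a secreted glycoprotein, rose from 54.7 ± 7.20 to 307 ± 59.1 CPM (2.49 ± 0.31 log2 units, adjusted p = 0.0442). KIAA1671 rose from 1.44 ± 1.06 to 24.0 ± 2.80 CPM (4.07 ± 0.53, adjusted p = 0.0449, or 0.0679 with the block). WDHD1, a DNA replication protein, fell from 11.9 ± 1.45 to 0.175 ± 0.0937 CPM (-6.07 ± 0.78, adjusted p = 0.0442, or 0.121 with the block). WDHD1 is 1 of 13 genes under 0.5 CPM in all 3 ILC3b libraries, out of 8556 genes at 5 CPM or more in all 6 libraries of ILC3a and ILC1a (CPM on totals without TMM scaling). None of the lineage genes chosen in advance passed. In ILC3a and ILC3b, AHR stood at 369 ± 51.0 and 332 ± 16.4 CPM, IL22 at 734 ± 1097 and 276 ± 246 and GATA3 at 67.4 ± 10.1 and 80.5 ± 26.3. TBX21 stood at 0.233 and 0.419, EOMES at 1.82 and 1.45 and IFNG at 0.895 and 0.755 CPM. GZMB stood at 31.9 ± 6.49 and 34.1 ± 9.57 CPM and PRF1 at 11.9 ± 2.99 and 23.1 ± 26.8 CPM. TCF7 had 1223 ± 55.0 and 840 ± 143 CPM (-0.54 ± 0.19, adjusted p = 0.301), and IKZF3 had 1.56 ± 0.488 and 12.5 ± 12.2 CPM (3.01 ± 1.01, adjusted p = 0.294).

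As a group, NK receptors were higher in ILC3b (camera adjusted p = 1.33e-07, and 0.00641 with an estimated correlation). Of 22 members 0 passed over all genes tested and 9 rose adjusted over the list alone, among them the inhibitory receptor TIGIT (12.3 ± 4.43 to 109 ± 67.6 CPM, 3.16 ± 0.48) and KLRC2 (5.81 ± 2.69 to 27.8 ± 12.1 CPM, 2.25 ± 0.45). Effector and cytotoxic genes were higher by camera (adjusted p = 0.000892), with 3 of 19 passing adjusted over the list alone: CST7, NKG7 and GZMA, at 10.6, 23.2 and 16.1 CPM in ILC3a and 46.1 ± 33.3, 71.5 ± 47.2 and 35.7 ± 15.6 CPM in ILC3b. That list's call was lost with an estimated correlation (adjusted p = 0.251 with an estimated correlation). Mitochondrially encoded genes, a measure of RNA quality and cell state, were higher by camera (adjusted p = 1.41e-18, but adjusted p = 0.218 with an estimated correlation), with 7 of 13 passing adjusted over the list alone, for example MT-CO2 at 3106 ± 785 and 5570 ± 1128 CPM. Further camera calls, all up and none with a member past the threshold over all genes, were checkpoint receptors (adjusted p = 0.0360, and adjusted p = 0.301 with an estimated correlation), the ribosomal proteins (0.000608, and adjusted p = 0.660 with an estimated correlation), erythroid genes (0.00118, and adjusted p = 0.225 with an estimated correlation) and oxidative phosphorylation (0.0462, and adjusted p = 0.660 with an estimated correlation). The last had an adjusted p of 0.0959 with the block, and glycolysis went from 0.0854 to 0.0455 with it (adjusted p = 0.660 with an estimated correlation). In the checkpoint list 1 member rose (TIGIT) and 1 fell (BTLA) adjusted over the list alone. The ILC3 program, with 0 of 20 members past either threshold, had a camera adjusted p of 0.971, a median below 0 and a test direction above 0. Camera's directions here are relative to a median log2 fold change over all genes of -0.633 in limma voom. The median in edgeR was 0.04 for the ribosomal proteins and 0.08 for oxidative phosphorylation, so neither list rose in itself. In fry, which tests each list alone, they had adjusted p = 0.824 and 0.985.

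In edgeR's test 4 genes differed, 3 higher and 1 lower in ILC3b, with 1850 genes at an unadjusted p under 0.05. The count was 3 with the block (ITGAE, NELL2 and AOAH, the last named after its values were seen, at 10.9 ± 3.27 and 61.9 ± 38.9 CPM). A fit of the compared libraries alone gave 0 genes (1069 at an unadjusted p under 0.05), while DESeq2 gave 683 (175 higher and 508 lower) and limma voom 228 (13 higher and 215 lower), so the balance turned to lower genes. EdgeR's count of 4 became 344 without ILC3b replicate 2 (39 higher and 305 lower) and 14 without ILC3b replicate 3 (4 and 10), and 2, 2 and 0 without ILC3a replicate 1, 2 or 3. It was 1 without any single ILC1b library, 1, 1 and 2 without ILC1a replicate 1, 2 or 3, and 0 without any whole batch.

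ILC1b against ILC3b compares cells sorted as CD300LF negative and CD300LF positive within the CD103-positive, CD196-positive gate. GZMB rose from 34.1 ± 9.57 to 1023 ± 129 CPM (4.91 ± 0.32 log2 units, adjusted p = 0.000201), IFNG from 0.755 ± 0.296 to 113 ± 77.5 CPM (7.25 ± 0.63, adjusted p = 0.00184) and PRF1 from 23.1 ± 26.8 to 552 ± 217 CPM (4.59 ± 0.74, adjusted p = 0.0268). TBX21 rose from 0.419 ± 0.113 to 34.5 ± 19.9 CPM (6.32 ± 0.73, adjusted p = 0.00722) and EOMES from 1.45 ± 1.30 to 49.3 ± 13.2 CPM (5.13 ± 0.66, adjusted p = 0.0112). AHR fell from 332 ± 16.4 to 117 ± 35.0 CPM (-1.51 ± 0.23, adjusted p = 0.0220). In edgeR's fit of the compared libraries alone GZMB still passed (adjusted p = 0.0303). IFNG, TBX21, EOMES, PRF1 and AHR did not pass in that fit (adjusted p = 0.2475, 0.4607, 0.5393, 0.5393 and 0.5393). IKZF3 had 12.5 ± 12.2 and 146 ± 114 CPM (adjusted p = 0.159), TCF7 840 ± 143 and 497 ± 96.1 CPM (adjusted p = 0.118), IL22 276 ± 246 and 15.8 ± 26.2 CPM (adjusted p = 0.325) and GATA3 80.5 ± 26.3 and 83.4 ± 27.8 CPM (adjusted p = 0.978).

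Many of the genes with the highest fold changes at this step were nearly uncounted in ILC3b, whose libraries detected the fewest genes on average (15931 ± 1951 after thinning). GFI1B, LEF1 and TFEB, all transcription factors, had 0 counts in ILC3b and 15.5 ± 5.08, 10.1 ± 0.887 and 10.0 ± 12.1 CPM in ILC1b, at least 189-fold, 126-fold and 116-fold higher. FCRL6 rose from 0.187 to 130 ± 98.2 CPM (9.14 ± 1.16). Genes with 1 to 3 counts in ILC3b included NHS (26.0 ± 23.2 CPM in ILC1b, ratio 947, 169 to 37430), the receptor kinase EPHA1 (38.0 ± 26.3, ratio 681, 188 to 5627), FCRL2 (38.0 ± 19.0, ratio 716, 198 to 5919) and the coreceptor CD8A (33.1 ± 39.6, ratio 579, 160 to 4788). They further included ADRB1 (37.1 ± 17.7, ratio 450, 154 to 2185), the ion channel TMEM206 (13.5 ± 10.2, ratio 523, 93.4 to 20700), DRAXIN (24.6 ± 12.8, ratio 445, 123 to 3684) and SLAMF8 (29.9 ± 14.9, ratio 371, 127 to 1802). TMEM206, at 13.4 ± 1.49 CPM in ILC3a, is another of the 13 genes missing from the ILC3b libraries. With the block, TFEB, NHS, CD8A, DRAXIN and SLAMF8 no longer passed (adjusted p = 0.110, 0.109, 0.0841, 0.0841 and 0.0841). Genes that fell included CSF2, the cytokine GM-CSF (257 ± 141 to 35.1 ± 17.0 CPM, -2.87 ± 0.54), SLC40A1, the iron exporter ferroportin (76.0 ± 39.4 to 1.30 ± 0.967 CPM, -5.85 ± 0.89), the netrin receptor relative NEO1 (59.4 ± 34.9 to 0.799 ± 0.559 CPM, -6.21 ± 0.94) and ELOVL6, a fatty acid elongase (539 ± 353 to 72.3 ± 14.1 CPM, -2.90 ± 0.39). AFF3 fell from 132 ± 22.7 to 21.2 ± 8.74 CPM, VWA5A from 1046 ± 458 to 183 ± 36.1 CPM and PPFIBP1 from 73.5 ± 13.3 to 13.1 ± 2.08 CPM. ROM1 fell from 12.3 ± 9.57 CPM to 2 counts (ratio 242, 66.7 to 2005). TOX2 (115 ± 29.4 to 4.70 ± 3.29 CPM), KIAA1324 (1086 ± 531 to 44.4 ± 32.3 CPM), ST6GALNAC3 (13.0 ± 5.76 to 0.261 ± 0.225 CPM) and the kinase PRKCE (12.9 ± 2.75 to 0.366 ± 0.298 CPM) fell as well, and had adjusted p-values of 0.0617, 0.0640, 0.0633 and 0.0990 with the block.

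By list, 7 of 19 effector and cytotoxic genes rose over all genes tested and 16 adjusted over the list alone, with 0 falling (camera adjusted p = 5.46e-15, and 0.00833 with an estimated correlation). GZMH rose from 0.792 to 60.4 ± 48.4 CPM. Of 20 ILC3 program genes, CSF2, AHR and the stem cell factor receptor KIT (1094 ± 87.0 to 275 ± 58.5 CPM) fell over all genes tested and 12 adjusted over the list alone, with 0 rising (camera adjusted p = 6.05e-15, and 0.00402 with an estimated correlation). Of 22 NK receptors, 3 rose, and 9 adjusted over the list alone (camera adjusted p = 6.02e-05, and 0.0103 with an estimated correlation). Those past the threshold over all genes were FCGR3A (0.399 to 49.4 ± 26.2 CPM), KLRC2 (27.8 ± 12.1 to 198 ± 38.3 CPM) and KLRD1, the CD94 receptor chain (347 ± 102 to 1190 ± 310 CPM). Their adjusted p-values were 0.0313, 0.0268 and 0.0313, or 0.0640, 0.0551 and 0.0755 with the block. Of 15 residency genes ZNF683 rose, from 3.39 to 945 ± 684 CPM, and 6 rose adjusted over the list alone (camera adjusted p = 0.00434, but adjusted p = 0.0569 with an estimated correlation). Of 40 transcription factors 5 rose and 2 fell, and 7 rose and 8 fell adjusted over the list alone (camera adjusted p = 0.883). BCL11B was among those that rose, from 0.175 to 32.8 ± 29.1 CPM. LEF1 was the 1 egress gene of 12 that rose, and TCF7 fell adjusted over the list alone (camera adjusted p = 0.678). Among other-cell lists, circulating NK genes (2 of 6 rose, GZMH and FCGR3A, and 4 adjusted over the list alone) were higher (camera adjusted p = 0.00198, but adjusted p = 0.0948 with an estimated correlation). T-cell genes (1 of 14 rose, CD8A, and 4 adjusted over the list alone) were also higher (0.0229, but adjusted p = 0.410 with an estimated correlation). Myeloid genes (0 of 8 passed, and 3 fell adjusted over the list alone) were lower (0.0214, but adjusted p = 0.274 with an estimated correlation). Mitochondrially encoded genes (0 of 13) were lower by camera (0.00163, but adjusted p = 0.607 with an estimated correlation), and the ribosomal proteins (0 of 37) and immediate early genes (0 of 24) higher (0.0484 and 0.0229, but adjusted p = 0.803 and adjusted p = 0.607 with an estimated correlation). The ribosomal call was also lost with DESeq2's size factors (0.0963).

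In edgeR's test 111 genes differed, 84 higher and 27 lower in ILC1b, and 68 with the block (43 higher and 25 lower), of which 55 were among the 111. A fit of the compared libraries alone called 1 gene, GZMB (adjusted p = 0.0303). Another split of the same 6 libraries, with ILC3b replicates 1 and 3 and ILC1b replicate 1 on one side, called 179 genes, more than the real 111. EdgeR's count of 111 became 177 and 611 without ILC3b replicate 1 or 2, and 29, 33 and 38 without ILC3a replicate 1, 2 or 3. It was 38, 43 and 42 without ILC1a replicate 1, 2 or 3, and 5, 7 and 2 without batch 1, 2 or 3.

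ILC1a against ILC1b compares cells sorted as CD196 negative and CD196 positive within the CD103-positive, CD300LF-negative gate. RTKN2 fell from 22.4 ± 4.65 to 2.08 ± 0.226 CPM (-3.43 ± 0.37 log2 units, adjusted p = 0.0305). It was the 1 gene called over all genes tested. AHR had 117 ± 35.0 CPM in ILC1b and 54.5 ± 6.04 in ILC1a (adjusted p = 0.231). EOMES had 49.3 ± 13.2 and 154 ± 37.2 CPM (adjusted p = 0.544), GZMB 1023 ± 129 and 2050 ± 680 CPM (adjusted p = 0.414), PRF1 552 ± 217 and 1220 ± 93.8 CPM (adjusted p = 0.913) and IFNG 113 ± 77.5 and 254 ± 79.2 CPM (adjusted p = 0.659). TBX21 had 34.5 ± 19.9 and 47.3 ± 9.12 CPM, IKZF3 146 ± 114 and 339 ± 41.8, TCF7 497 ± 96.1 and 317 ± 47.5, GATA3 83.4 ± 27.8 and 59.9 ± 3.07, and IL22 15.8 ± 26.2 and 1.24 ± 1.00, and none passed.

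As a group the ILC3 program was lower in ILC1a than in ILC1b (camera adjusted p = 9.21e-10, and 0.0174 with an estimated correlation). Of its 20 members 0 passed over all genes tested and 10 fell adjusted over the list alone, among them KIT (275 ± 58.5 to 50.2 ± 25.9 CPM) and CCL20 (20.9 ± 14.3 to 1.30 ± 0.335 CPM). Effector and cytotoxic genes were higher by camera (adjusted p = 0.000827, but adjusted p = 0.298 with an estimated correlation), with 0 of 19 past either threshold. The ribosomal proteins were lower (1.86e-29, but adjusted p = 0.141 with an estimated correlation), with 0 of 37 past the threshold over all genes and 12 adjusted over the list alone, such as RPL11 (937 ± 89.3 to 587 ± 40.3 CPM). Oxidative phosphorylation genes (0 of 30) and mitochondrially encoded genes (0 of 13) were lower (7.98e-05 and 1.07e-07, but adjusted p = 0.392 for both with an estimated correlation). T-cell genes were lower (0.0331, but adjusted p = 0.392 with an estimated correlation), with 0 of 14 past the threshold over all genes and 2 that fell adjusted over the list alone, THEMIS and CD3E. The residency and circulating NK lists went from adjusted p-values of 0.210 for both to 0.0237 and 0.0402 (both up) with the block, and had adjusted p = 0.392 and 0.397 with an estimated correlation.

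The count of 1 gene in edgeR's test went with 1099 genes at an unadjusted p under 0.05, against 300 called by DESeq2 (159 higher and 141 lower in ILC1a) and 48 by limma voom (43 and 5), and 0 by edgeR in a fit of the compared libraries alone (1027 unadjusted). With the block 5 genes were called: RTKN2, CCR6 and, named after their values were seen, NRP1 (39.4 ± 34.9 to 2.01 ± 2.17 CPM), SPOCK2 (253 ± 11.2 to 89.6 ± 2.97 CPM) and PCDH9 (185 ± 72.3 to 12.1 ± 9.77 CPM). EdgeR's count of 1 became 0 without ILC3a replicate 1, 2 or 3, ILC3b replicate 2, ILC1b replicate 2 or 3, ILC1a replicate 1 or 3, or any whole batch, 2 without ILC3b replicate 3 or ILC1b replicate 1, and 3 without ILC1a replicate 2. Without a low-count filter the count was 12, and with the stricter one 2.

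Among the remaining pairs, 94 genes differed between ILC1b and ILC3a (64 higher and 30 lower in ILC1b) and 339 between ILC1a and ILC3b (206 higher and 133 lower in ILC1a). For the first pair DESeq2 called 282 higher and 365 lower and limma voom 114 and 218. For the second, limma voom with sample quality weights called 53 higher and 124 lower and the fit of the compared libraries alone 19 and 30, so in both pairs the balance turned with the setting. The first count was 24, 27 and 17 without ILC3a replicate 1, 2 or 3 and 60, 55 and 60 without ILC1b replicate 1, 2 or 3. It was 191 without ILC3b replicate 1, and 28, 1 and 7 without batch 1, 2 or 3. The second was 178, 175 and 182 without ILC3a replicate 1, 2 or 3, 1003 without ILC3b replicate 2 and 516 without ILC1b replicate 1. It was 110, 129 and 108 without ILC1a replicate 1, 2 or 3, and 117, 23 and 2 without batch 1, 2 or 3. The joint test called 254 genes as differing among the 4 populations. That count was 106, 113 and 109 without ILC3a replicate 1, 2 or 3, 96, 110 and 91 without ILC1a replicate 1, 2 or 3, 613 without ILC3b replicate 2, and 55, 17 and 7 without batch 1, 2 or 3.

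To place the middle populations between the ends, each batch was scored on genes chosen in the other batches, on a scale from 0 for ILC3a to 1 for ILC1a. The genes of the sort markers were not removed from that choice, so the gate itself may set part of the positions. Sparse detection in the middle libraries may set part of the positions too, which was not tested. ILC3b lay at 0.16 ± 0.06 and ILC1b at 0.75 ± 0.11 (SD, n = 3 batches). In batch 1 (93 genes) the positions were 0.12 and 0.878, in batch 2 (23 genes) 0.138 and 0.683, and in batch 3 (15 genes) 0.23 and 0.696. ILC1b was nearer ILC1a than ILC3b was in 3 of 3 batches, by 0.59 ± 0.15. The exact two-sided sign-flip permutation test gave p = 0.25, the smallest that 3 batches allow. On the genes higher in ILC1a, ILC3b lay at 0.19 ± 0.09 and ILC1b at 0.82 ± 0.06, and on those lower in ILC1a, at 0.08 ± 0.03 and 0.58 ± 0.25. The planned choices of genes kept ILC1b nearer ILC1a on the higher genes in every batch with genes of both kinds. That order turned in batches 1 and 2, but not in batch 3, with genes called between the end populations alone, a choice made after the data were seen. ILC1b then lay at 0.736, 0.552 and 0.711 on the higher genes and at 1.028, 0.855 and 0.66 on the lower genes in batches 1 to 3. ILC3b lay at -0.438, -0.009 and -0.051 on the higher genes and at 0.536, 0.177 and 0.262 on the lower genes, so its order turned too and its mean of 0.1 averages values far apart. The mean ILC3b position was also 0.1 with the 200 genes of smallest p, a planned choice. With it the ILC3b order turned in batch 1 only (-0.028 on the higher and 0.176 on the lower genes). Genes from the fit with the block turned it in batch 1 as well (0.099 and 0.158).

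**Figure D4:**
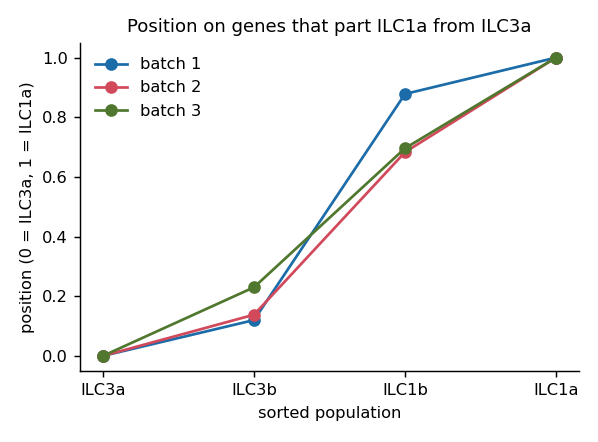
Position of each population between ILC3a (0) and ILC1a (1) on genes chosen in the other batches, with 1 line per batch; the ends are 0 and 1 by construction. ILC3b lies between 0.12 and 0.23 and ILC1b between 0.683 and 0.878.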

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

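Sample quality weights, the pairwise fit with a block, the omission of libraries outside a pair and position genes from the end populations alone were chosen after the data were seen. Counts of called genes are given in the order ILC1a against ILC3a, ILC3b against ILC3a, ILC1b against ILC3b, ILC1a against ILC1b, ILC1b against ILC3a, ILC1a against ILC3b and the joint test, where edgeR's reported counts were 198, 4, 111, 1, 94, 339 and 254. DESeq2 called 684, 683, 1445, 300, 647, 1857 and 1793, and limma voom 447, 228, 217, 48, 332, 979 and 902. With sample quality weights limma voom called 2595, 0, 0, 0, 233, 177 and 2476; the counts of 0 had 1075, 932 and 1752 genes at an unadjusted p under 0.05. The weights were 1.646 to 3.487 for the libraries of ILC3a and ILC1a and 0.119 to 0.823 for the others. A fit of the compared libraries alone called 1998, 0, 1, 0, 82 and 49 (1069, 526 and 1027 unadjusted for the counts of 0, 1 and 0), and with the replicate block added 2238, 0, 0, 0, 6 and 1 (795, 513 and 974 unadjusted). The replicate block in the fit of all libraries gave 218, 3, 68, 5, 103, 275 and 209; beyond the calls named beside their results it changed no other call of a gene in a comparison where the text gives it, nor of a list. DESeq2's size factors gave 199, 4, 108, 1, 98, 365 and 254. No filter on low counts gave 225, 4, 93, 12, 103, 279 and 313, and the stricter filter 228, 4, 127, 2, 115, 348 and 264. Fewer genes tested or fewer libraries follow from the construction of some settings. The fit of all libraries uses 1 spread per gene for every population. Replicates differed by 92.8 to 273.1 in chi-square per gene in ILC3b and ILC1b and by 40.7 to 54.9 in the ends. A shared spread is thus strict for ILC1a against ILC3a and lenient for ILC1b against ILC3b. In the simulation, recovery of 4-fold changes was 18% with the spread of all libraries and 86% with that of the end libraries. How far this accounts for the differences was not tested, nor were other causes.

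Leaving out 1 library or batch moved the counts over 15 to 363, 0 to 344, 2 to 611, 0 to 3, 1 to 191, 2 to 1003 and 7 to 613. Without a whole batch each population keeps 2 libraries. For the positions, 1 batch score at a time was left out of the mean, without a new fit or choice of genes. The mean for ILC3b then ranged from 0.13 to 0.18 and that for ILC1b from 0.69 to 0.79. These ranges restate the batch scores, and no single library was left out for them. ILC3b moved from 0.16 to 0.1 both with the 200 genes of smallest p and with genes from the end populations alone, and other choices gave 0.16 to 0.18; for ILC1b they gave 0.75 to 0.78. With the block, 7 genes were left for batch 3, with 0 lower in ILC1a.

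Of lists past the threshold in the 4 main comparisons (14, 7, 11 and 8), an estimated correlation kept 5, 1, 3 and 1 and fry, which tests each list alone for a common direction, 7, 1, 6 and 3. In all fry called 7, 3, 7 and 3, the block 15, 7, 12 and 10 and DESeq2's size factors 14, 7, 10 and 8. Over all settings of 151 pairs of a gene and a comparison (genes of the naming rule, sort markers and genes named after their values were seen), the call over all genes was the same in 1984, lost in 689 and gained in 43. For 219 pairs past the threshold over a list alone it was the same in 3318, lost in 63 and gained in 502. The sign of the fold change turned in 31 settings of 8 pairs, none past the threshold in either fit. Sparse detection limits what can be said of genes with few counts in ILC3b and ILC1b. Their libraries had 8328763 to 17483570 counts and detected fewer genes also at equal totals.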

Other observations

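Of 25 cytokine receptors 2 rose and 4 fell in ILC1a against ILC3a, and 5 rose and 8 fell adjusted over the list alone (camera adjusted p = 0.541). IL2RB, the shared receptor chain for IL-2 and IL-15, rose from 598 ± 47.2 to 2685 ± 738 CPM, and IL10RA from 5.94 ± 2.64 to 405 ± 63.4 CPM. IL1R1 fell from 310 ± 55.8 to 5.75 ± 5.52 CPM, IL7R from 4990 ± 1619 to 382 ± 261 CPM and IL4R from 442 ± 65.6 to 147 ± 21.3 CPM, along with IL23R. Of 15 chemokine receptors, CXCR3, which guides type 1 lymphocytes, rose from 10.4 ± 0.899 to 397 ± 89.0 CPM and CCR7 fell, with 4 rising and 5 falling adjusted over the list alone (camera adjusted p = 0.564). Of 21 checkpoint and costimulatory receptors 2 rose and 2 fell, and 8 rose and 6 fell adjusted over the list alone (camera adjusted p = 0.542). TIGIT rose from 12.3 ± 4.43 to 427 ± 82.7 CPM and CD27 from 1.62 ± 0.223 to 101 ± 51.8 CPM (adjusted p = 0.0332, or 0.0806 with the block), while NT5E and ICOS (204 ± 106 to 21.6 ± 5.52 CPM) fell. At the ILC3b to ILC1b step IL2RB (947 ± 119 to 1959 ± 199 CPM) and IL10RA (3.28 ± 4.86 to 195 ± 98.2 CPM, adjusted p = 0.0405, or 0.0938 with the block) rose. In those 3 lists 4 rose and 4 fell, 4 rose and 0 fell, and 5 rose and 0 fell adjusted over the list alone.

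The invariant chain CD74 was the 1 MHC class II gene of 7 that fell in ILC1a against ILC3a, from 3288 ± 489 to 1470 ± 148 CPM, and the list was lower by camera (adjusted p = 0.00521, but adjusted p = 0.0816 with an estimated correlation). Of 36 interferon response genes BST2, the antiviral protein tetherin, fell from 646 ± 32.4 to 235 ± 17.1 CPM, and 2 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.360). Proliferation genes were higher in ILC1a by camera (adjusted p = 3.10e-09, but adjusted p = 0.155 with an estimated correlation). Of 30 members 0 passed over all genes tested and BUB1 and MCM5 rose adjusted over the list alone, and MKI67 stood at 7.86 ± 6.50 and 46.2 ± 11.7 CPM. The list was also higher in ILC1b than in ILC3b, where BUB1 rose from 0.554 to 12.9 ± 7.17 CPM (adjusted p = 0.0452, or 0.132 with the block) and 6 members rose adjusted over the list alone (camera adjusted p = 0.0229, but adjusted p = 0.607 with an estimated correlation). In ILC1a against ILC1b its camera adjusted p was 0.000827, but adjusted p = 0.397 with an estimated correlation, and that of MHC class II 0.0331 (down), but adjusted p = 0.298 with an estimated correlation. In ILC1a against ILC3a the glycolytic aldolase ALDOC fell from 250 ± 86.1 to 54.7 ± 0.644 CPM (1 of 20 glycolysis genes, camera adjusted p = 0.564). Ribosomal proteins and oxidative phosphorylation were lower and immediate early genes higher by camera (adjusted p = 1.48e-06, 0.0381 and 0.00192), with 0 members past either threshold and adjusted p = 0.363, 0.581 and 0.363 with an estimated correlation. Mitochondrially encoded genes (0 of 13) had a camera adjusted p of 0.541. The TGF-beta response list (21 genes, TGIF1 lower adjusted over the list alone) had a camera adjusted p of 0.541, and the Notch list (14 genes, RBPJ lower adjusted over the list alone and, with the block, over all genes at adjusted p = 0.00326) 0.160, or 0.0463 (down) with the block (adjusted p = 0.299 with an estimated correlation). The Notch list in ILC1b against ILC3b had 0.134, or 0.0185 (down) with the block (adjusted p = 0.323 with an estimated correlation).

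The median, the mean and the test of a list differed in sign for several lists, none of which passed. In ILC1a against ILC3a these were egress, transcription factors, chemokine receptors, checkpoints, interferon response, mitochondrially encoded genes and gamma-delta T-cell receptor. In ILC3b against ILC3a they were the ILC3 program, transcription factors, Notch, MHC class II, interferon response, immediate early genes, T cells, B cells and epithelial genes. In ILC1b against ILC3b they were egress, checkpoints, glycolysis, oxidative phosphorylation and erythroid genes, and in ILC1a against ILC1b egress, chemokine receptors, TGF-beta response, Notch, interferon response, glycolysis, immediate early genes, ILC2 and myeloid genes. The direction of camera is relative to all other genes. Their median log2 fold change in limma voom was -0.032, -0.633, 0.192 and 0.262 in these 4 comparisons, in the order given.

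Of the tests that follow, those of sequencing depth, of the ratio of observed to expected missing genes, of B cells, of circulating NK cells and of gained against lost genes were chosen after the result was seen.

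Libraries of the middle populations detected fewer genes, and WDHD1 and 12 other genes were missing (under 0.5 CPM on totals without TMM scaling) from all 3 ILC3b libraries among 8556 genes at 5 CPM or more in all 6 end libraries. Depth does not account for it, since at equal totals the lowest end library detected 1344 genes more than the highest middle library. The advance bound on the 13 shared missing genes, set against triples mixed from ILC3b and ILC1b libraries (up to 40), was wrong because single libraries miss from 0.105% (ILC1b replicate 3) to 18.3% (ILC3b replicate 1) of these genes, so neither random loss from little RNA nor absence in ILC3b could be decided from it. Scaled to each library's own loss, the 13 were 3.615 times the number from independent loss. That lay inside the 2.694 to 6.134 of the 7 mixed triples with an expectation of at least 1. The ratio cannot decide on an excess particular to ILC3b, since the mixed triples hold ILC3b libraries too. Loss of molecules in libraries made from few cells and absence in ILC3b both stay open for the missing genes, WDHD1 and TMEM206 included. A difference between the sorted populations in RNA content, which was not tested, stays open too.

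Several genes known from other lymphocytes were higher in ILC1a than in ILC3a, among them CD3G, MS4A1 and FCGR3A, despite a gate on CD56 and NKp44. CD3G was highest in ILC1b, with means of 7.20, 91.8, 343 and 149 CPM from ILC3a to ILC1a. The tests below cover ILC1a against ILC3a only, and other lymphocytes among the sorted ILC3b and ILC1b were not tested. For B cells among the sorted ILC1a, their other genes at 1 CPM or more had a median log2 ratio of -1.49. CD79A (37.9 CPM in ILC3a and 4.35 in ILC1a) and BANK1 (29.2 and 1.47) did not rise with MS4A1. CD79B stood at 31.2 and 33.6 CPM, and FCRL1, at 1.94 and 17.8, rose as MS4A1 did. With its genes split, the test cannot decide on B cells, which stay open. Circulating NK cells that express FGFBP2, CX3CR1, S1PR5 and PRSS23 are argued against as the source of FCGR3A. These genes stood at 1.44, 1.34, 1.10 and 0.0200 CPM in ILC1a beside 171 CPM of FCGR3A, a highest ratio of 0.008418. NK cells low in these genes are not covered by the test and stay open. Of 6 measured genes of the circulating NK list, 5 rose adjusted over the list alone. For T cells, the summed CPM of alpha and beta variable segments was 3.71 in ILC3a and 3.07 in ILC1a, a gain of -0.00452 of that of CD3G. The sum changed by -0.641 ± 1.10 CPM (SE) where the bound set in advance was 14.2 CPM, so the counted segments showed no gain. It cannot decide on T cells with alpha and beta receptors, because the segment CPM that such cells would give in this counting is not known. The test rests on the alpha segments, of which 29 of 54 were counted with 546 counts in all, as 52 beta segments hold 10 counts and TRBC1 has 0. Gamma-delta T cells, whose segments are outside that sum, stay open (TRDC 869 ± 174 and 1206 ± 141 CPM in ILC3a and ILC1a). Expression of these genes by ILC1a themselves also stays open, as a hypothesis.

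On the scale from ILC3a to ILC1a, ILC1b lay nearer ILC1a on the higher than on the lower genes, by 0.23 ± 0.19 and in 3 of 3 batches, which raised the hypothesis that gains come before losses. With genes chosen from the end populations alone the difference was -0.18 ± 0.20, above 0 in 1 of 3 batches, within its spread. The planned choices gave differences of 0.17 with the 200 genes of smallest p, 0.23 with a log2 fold change of at least 2 and 0.25 with DESeq2's size factors (3 of 3 batches each) and 0.20 with the block (2 of 2 batches). The order depends on the choice of genes. A gene missing from a middle library also scores towards ILC3a if higher in ILC1a, and towards ILC1a if lower. ILC3b replicates 1, 3 and 2 missed 18.3%, 4.01% and 0.912% of the 8556 genes above. With genes from the end populations alone they lay at -0.438, -0.051 and -0.009 on the higher genes and at 0.536, 0.262 and 0.177 on the lower. ILC1b on the higher genes did not follow its missing shares. The part of sparse detection was not tested, and the hypothesis stays open.

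For the pairs of populations, splits of the 6 libraries that part all same-numbered pairs number 4 with the real one, too few for a share under 0.05, and only the real one, 1 of the 4, reached its own count in each pair. The real counts and the highest other were 198 and 0 for ILC1a and ILC3a, 4 and 0 for ILC3b and ILC3a, 111 and 4 for ILC1b and ILC3b, 1 and 0 for ILC1a and ILC1b, 94 and 0 for ILC1b and ILC3a, and 339 and 0 for ILC1a and ILC3b. Among all 10 splits of ILC1b and ILC3b, the one that groups ILC3b replicates 1 and 3 with ILC1b replicate 1 called 179 genes, more than the real 111, so the 6 libraries hold a structure across the populations. These 3 also had the largest missing shares (18.3%, 4.01% and 4.47%), but a link between the shares and the calls was not tested. For the joint test, 1 of 100 splits within batches, the real one, gave as many genes (254, highest other 137). That share is under 0.05 and is the smallest that 100 splits allow, so a chance split is an unlikely source of that count.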
